A study of Homo sapiens with 12 samples.

How the data were processed

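Acute myeloid leukemia (AML) cells from 2 patients were transduced with lentivirus carrying XBP1 or, as the control, human CD25 that does not signal, each with a ZsGreen marker (per the labels' protocols). ZsGreen-positive cells were sorted 72 hours after transduction, RNA was isolated with TRIzol, and libraries were made with the Illumina TruSeq Stranded mRNA kit (per the labels' protocols). The labels give the groups and replicate numbers: 4 groups of 3 libraries each. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, made by the authors with STAR and Cufflinks on the hg38 build, per the submitters' processing notes. Those notes give no versions, no annotation and no division of work between the tools. No read counts were used here, and the depth of each library and its counting error are unknown. The summed FPKM per library lay between 952536 and 1102979, and mitochondrial genes took between 10.3% and 14.3% of it.

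Each library listed 57816 gene IDs, which were joined by ID. GENCODE 29 (GRCh38) holds 52335 of them, 29841 in the same version, and gave positions and gene types. Symbols are those of the deposited files, some of them older than those of GENCODE 29. Genes were tested when they reached 1 FPKM in at least 3 of the 12 libraries. Members of a list that did not pass this filter were not tested, and counts per list are out of the members tested. Genes specific to the sex chromosomes that could bear on a donor were left out of every test. Genes of small RNAs recognized by symbol, whose values in such libraries are unreliable, were left out except in the alternative that kept them. Values were analyzed as log2(FPKM + 1), with no further scaling.

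The fit was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings). All 12 libraries entered 1 model with a mean per group, so that the groups share an estimate of the spread. The contrasts were XBP1 minus control in AML-A, the same in AML-B, the mean of these, and their difference (AML-B effect minus AML-A effect). Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested genes and no fold minimum. SE values come from this fit. The vector genes also had an exact permutation test. The 21 gene lists and 7 marker lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 28 lists within a contrast. Beside it stood camera with an estimated correlation and fry, which tests whether a list moves on balance in a direction without reference to other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 loaded and drew the data.

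The model, filter, contrasts, lists, alternatives and the rule for named genes were chosen before the data were examined. XBP1, IL2RA and ERN1 were always named. For AML-A, AML-B and their mean, the rule took the 10 genes with the largest change each way among those past the threshold. Such a gene also needed every XBP1 library beyond every control library, a symbol listed once and a mean of at least 2 FPKM. For the difference it took 5 each way, and in each list up to 4 members past the threshold with the largest change, or otherwise the 2 most abundant. Immunoglobulin, T cell receptor and HLA genes and genes with common germline deletions were not named, and the text leaves out 1 gene that the rule took for AML-B. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, and the replicate number as a block. Further alternatives were each AML sample fitted alone, limma without its trend and robust settings, library weights, small RNAs kept, a 2-fold minimum, and leaving out each library in turn. A fit on protein-coding genes was added after seeing the data.

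The procedure was tested on simulated data of the same design and 15116 genes. Of 67 genes changed 2-fold it recovered 92.5% in AML-A and 89.6% in AML-B. There were 7 false calls in AML-A, 18 in AML-B, 15 in the mean and 0 in the difference. The simulated noise was independent between genes and had the spread of the model, equal in all groups. In the data the median SD per gene was 0.124 and 0.137 log2 units in the XBP1 groups of AML-A and AML-B. It was 0.090 and 0.094 in their controls, so that these rates hold for the simulated data only. No pair of libraries of a group was identical, and no protein-coding gene with a mean of at least 20 FPKM was at 0 in any library.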

Results

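Messenger RNA was profiled in acute myeloid leukemia (AML) cells from 2 patients, called AML-A and AML-B here. The cells were transduced with a lentivirus carrying XBP1, the transcription factor of the IRE1α branch of the unfolded protein response, or with a control lentivirus carrying a CD25 protein that does not signal. The labels do not state whether the vector carried the spliced form of XBP1, which is the active factor, and FPKM per gene does not tell the forms apart. Cells were taken 72 hours after transduction and sorted for the ZsGreen marker of the vector. AML-A was cultured with stem cell factor (SCF) at 50 ng/ml. The AML-B medium held SCF and FLT3 ligand at 50 ng/ml each and GM-CSF, IL-3 and IL-6 at 20 ng/ml each, so that patient and medium cannot be separated. Each of the 4 groups had 3 libraries, 12 in all. The deposited values were FPKM, whose sum per library lay between 952536 and 1102979, and the read depth behind them is unknown. Between 14259 and 14613 genes per library reached 1 FPKM. Replicates correlated across genes at Pearson's r between 0.982 and 0.991. In a principal component analysis of the 15116 genes tested, the leading component (50.1% of the variance) separated the AML samples, and the next (19.5%) separated XBP1 from control libraries. On the leading component the AML-A control libraries lay between -38.88 and -37.10 and the AML-B libraries between 29.38 and 33.16, while the AML-A XBP1 libraries spread between -36.13 and -11.30. Whether the replicates are separate transductions is not stated, so that p-values measure the spread between these libraries, and nothing is said of patients in general. Fold changes are on the log2(FPKM + 1) scale, and values are means ± SD of 3 libraries unless stated.

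The vector genes were examined in every library, since they check the labels. XBP1 (ENSG00000100219.12, GRCh38 chromosome 22, 28794555 to 28800597, minus strand) rose in AML-A from 128 ± 0.63 to 365 ± 56.4 FPKM (mean ± SD, n = 3), a log2 fold change of 1.5 ± 0.15 (SE, adjusted p = 4.61e-05, limma). In AML-B it rose from 106 ± 1.75 to 173 ± 41.7 FPKM, a log2 fold change of 0.68 ± 0.15 (adjusted p = 0.038). The ratio of mean FPKM was 2.86 in AML-A and 1.64 in AML-B. The log2 effects differed by -0.82 ± 0.22 (AML-B minus AML-A, limma adjusted p = 0.0399), a call near the threshold. The AML-B XBP1 libraries held 192, 125 and 203 FPKM, all above the highest AML-B control at 107. IL2RA, the gene of CD25 (ENSG00000134460.11, GRCh38 chromosome 10, 6010689 to 6062370, minus strand), stood at 7817 ± 421 FPKM in the AML-A controls against 4.06 ± 0.585 in the AML-A XBP1 libraries. In AML-B the values were 4060.0 ± 130.3 and 1.92 ± 0.42 FPKM. Transcripts of the vector are counted in these values, since the control vector encodes CD25. IL2RA took 0.717% of the summed FPKM in the AML-A controls and 0.419% in those of AML-B. No group lacked a vector or carried an empty one. Every contrast therefore compares XBP1 with CD25, and an effect of CD25 or of vector load cannot be told from one of XBP1. ERN1, which encodes IRE1α (ENSG00000178607.11, GRCh38 chromosome 17, 64039142 to 64130819, minus strand), was at 4.73 ± 0.374 and 4.92 ± 0.873 FPKM in AML-A and at 2.06 ± 0.421 and 2.23 ± 0.893 in AML-B (adjusted p = 0.89 and 0.917). An exact permutation test of the 6 libraries of an AML sample gave p = 0.1 for XBP1 and for IL2RA in each AML sample, two-sided, the smallest value that 3 against 3 libraries allow. The limma call of XBP1 in AML-B rested on several libraries. It was lost without AML-A control replicate 1, 2 or 3 (adjusted p = 0.0588, 0.0619 and 0.0609), AML-A XBP1 replicate 3 (0.0622), AML-B control replicate 1, 2 or 3 (0.0748, 0.118 and 0.126) or AML-B XBP1 replicate 1 or 3 (0.0806 and 0.109), and adjusted p over all alternatives ran from 0.00269 to 0.14.

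**Figure D1:**
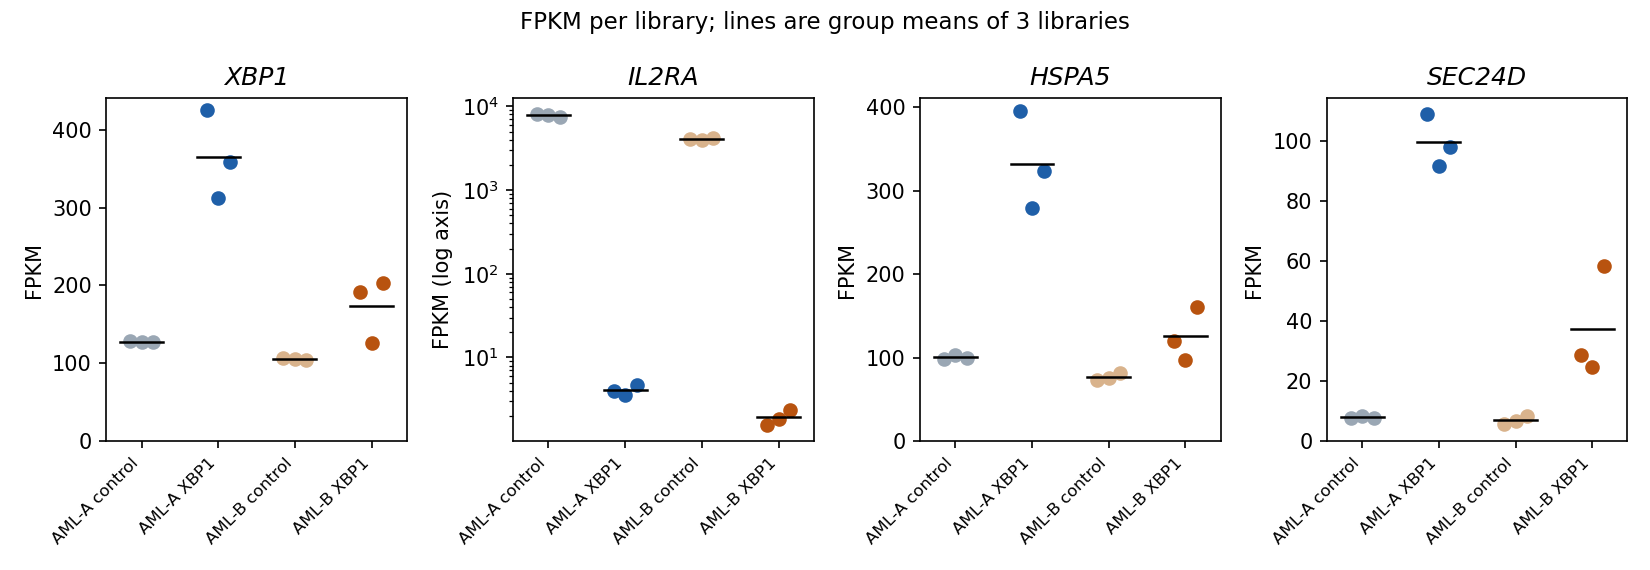
FPKM of XBP1, IL2RA, HSPA5 and SEC24D in each of the 12 libraries (points, colored by group), with the mean of 3 libraries per group as a line; the IL2RA axis is logarithmic and the others start at 0. XBP1 stood at 425, 312 and 359 FPKM in the AML-A XBP1 libraries and at 192, 125 and 203 in those of AML-B.

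With XBP1 in AML-A cells, most listed genes of the secretory pathway rose over the control vector, and many inflammatory genes fell. MZB1, an endoplasmic reticulum (ER) cochaperone of the B cell lineage, rose from 0.417 ± 0.133 to 35.9 ± 2.91 FPKM, a log2 fold change of 4.70 ± 0.20. SEC24D, a coat protein of ER export vesicles, rose from 7.86 ± 0.413 to 99.7 ± 8.85 FPKM (3.50 ± 0.24). KDELR3, a retrieval receptor for ER proteins, rose from 1.29 ± 0.237 to 24.7 ± 4.14 FPKM. DERL3, a factor of ER-associated degradation, rose from 5.88 ± 0.485 to 56.9 ± 8.04 FPKM. PGM3, an enzyme of hexosamine synthesis, rose from 3.75 ± 1.61 to 38.2 ± 12.2 FPKM. The protein disulfide isomerase PDIA2 rose from 0.217 ± 0.0995 to 13.1 ± 7.44 FPKM, and MEI1, a meiosis gene, from 2.32 ± 0.71 to 53.1 ± 3.59 FPKM. The ribonuclease gene ANG rose from 0.274 ± 0.259 to 10.1 ± 0.815 FPKM and the interferon-induced IFI27 from 0.68 ± 0.327 to 19.3 ± 15.9 FPKM. Besides IL2RA, the cytokine IL32 fell most, from 49.8 ± 9.69 to 9.25 ± 6.96 FPKM, a log2 fold change of -2.59 ± 0.50. SPP1 (osteopontin) fell from 20.9 ± 4.02 to 3.14 ± 1.58 FPKM and the apolipoprotein APOE from 20.4 ± 0.942 to 3.26 ± 1.15 FPKM. The myeloid integrin gene ITGAM fell from 9.1 ± 0.895 to 1.13 ± 0.272 FPKM. CD74, the invariant chain of antigen presentation, fell from 6.77 ± 1.32 to 0.93 ± 0.573 FPKM, and the chemokine CCL3 from 4.91 ± 0.956 to 0.57 ± 0.313 FPKM. PTGDS (prostaglandin D synthase) fell from 6.53 ± 1.93 to 0.508 ± 0.559 FPKM and the histone gene HIST1H2AC from 36.9 ± 2.02 to 9.16 ± 2.75 FPKM. The pseudogene CTD-2319I12.1 fell from 11.4 ± 0.562 to 2.28 ± 1.26 FPKM. All of these passed the limma test, with adjusted p between 2.39e-07 and 0.00932, and their XBP1 libraries all lay beyond all control libraries. AL132780.1 (ENSG00000207765.1), an ID that GENCODE 29 does not hold, was listed near 0 in the 3 AML-A controls and at 129.8, 402 and 505 FPKM in the XBP1 libraries. No fold is given for it, and whether it is a gene of a small RNA, whose values would be unreliable, is unknown.

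In all, 4345 of 15116 genes changed in AML-A (limma on log2(FPKM + 1), adjusted p under 0.05), 2609 higher and 1736 lower with XBP1, and 471 of them by at least 2-fold (376 higher, 95 lower). Of the changed genes, 3482 were protein-coding in GENCODE 29. The split between directions depended on the scaling: quantile normalization gave 2045 higher and 2455 lower genes, a share of 45.4% higher in place of 60%. Weighting the libraries gave 6881 genes. Of 104 genes that the rule for named genes or the lists took for AML-A, 14 lost their call without AML-A XBP1 replicate 2, 1 and 8 without XBP1 replicate 1 or 3, and 6, 12 and 12 without control replicate 1, 2 or 3.

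In AML-A 5 lists of ER and secretory functions were called higher, and the targets of the PERK branch were not called. All 24 tested genes of ER chaperones and folding enzymes rose, with a median log2 fold change of 1.36. The chaperone list counted 24 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 6.14e-20 and adjusted p = 0.14 with an estimated correlation. MANF, a secreted ER stress factor, rose from 72.2 ± 4.3 to 444 ± 21.5 FPKM, and the cochaperone SDF2L1 from 8.38 ± 0.292 to 44.5 ± 2.58 FPKM. The disulfide isomerase PDIA5 rose from 16.3 ± 2.1 to 67.2 ± 3.66 FPKM and PDIA4 from 52.6 ± 1.36 to 197 ± 7.5 FPKM. In ER-Golgi vesicle transport 34 of 35 genes rose (median 0.91). This transport list counted 34 higher and 1 lower genes adjusted over the list alone, with camera adjusted p = 5.36e-23 and adjusted p = 0.133 with an estimated correlation. Beside SEC24D and KDELR3, the cargo receptor LMAN1 rose from 23.1 ± 2.64 to 98.3 ± 9.87 FPKM and PREB from 26.7 ± 3.14 to 112 ± 7.35 FPKM. In ER translocation and N-glycosylation 30 of 31 genes rose (median 0.99). The translocation list counted 30 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 1.1e-20 and adjusted p = 0.14 with an estimated correlation. The translocon subunits SSR3 and SSR1 rose from 68.1 ± 0.85 to 327 ± 11.5 FPKM and from 70.2 ± 3.99 to 228 ± 6.01 FPKM. The signal peptidase subunit SEC11C rose from 42.5 ± 6.11 to 196 ± 19.4 FPKM, and SRPRB from 32.9 ± 1.42 to 98.6 ± 6.67 FPKM. In ER-associated degradation 15 of 21 genes rose and 1 fell (median 0.61). The degradation list counted 15 higher and 2 lower genes adjusted over the list alone, with camera adjusted p = 4.19e-09 and adjusted p = 0.115 with an estimated correlation. ERLEC1 rose from 31.4 ± 1.54 to 110.1 ± 12.5 FPKM, EDEM2 from 12 ± 0.454 to 41.5 ± 3.67 FPKM and HERPUD1 from 134 ± 4.06 to 392 ± 44.2 FPKM. In hexosamine and nucleotide-sugar synthesis 11 of 13 genes rose and 1 fell (median 0.94). The hexosamine list counted 11 higher and 1 lower genes adjusted over the list alone, with camera adjusted p = 3.29e-06 and adjusted p = 0.133 with an estimated correlation. GMPPB rose from 1.68 ± 0.117 to 17.8 ± 1.08 FPKM, GFPT1 from 3.44 ± 0.586 to 14.6 ± 0.694 FPKM and GMPPA from 20.8 ± 2.1 to 71.1 ± 1.77 FPKM. The targets of the PERK branch (ATF4 and CHOP) gave 0 calls among 22 genes by limma, over all genes or adjusted over the list alone. Of these genes 2 had an unadjusted p under 0.05, and camera gave adjusted p = 0.858. ATF4 itself stood at 549 ± 12.2 and 616 ± 108 FPKM, and SLC3A2 at 228 ± 7.92 and 220.4 ± 45.3. The PERK list was called lower without AML-A XBP1 replicate 1 (adjusted p = 0.0202) and higher without replicate 2 (0.0243).

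The cell cycle, interferon and sterol lists were also called higher in AML-A, and the inflammation, myeloid and lysosome lists lower. In the cell cycle list 25 of 30 genes rose (median log2 fold change 1.01). The cell cycle list counted 28 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 1.77e-13 and adjusted p = 0.368 with an estimated correlation. The mitotic genes CDC20 and BIRC5 rose from 10.9 ± 1.66 to 47.2 ± 7.76 FPKM and from 7.75 ± 2.24 to 31.9 ± 7.8 FPKM. UBE2C rose from 29.6 ± 5.1 to 109.7 ± 29 FPKM and PLK1, a mitotic kinase, from 11.9 ± 2.45 to 39.7 ± 6.2 FPKM. In the interferon response 15 of 22 genes rose and 1 fell (median 0.72). The interferon list counted 16 higher and 1 lower genes adjusted over the list alone, with camera adjusted p = 2.02e-05 and adjusted p = 0.472 with an estimated correlation. IFI6 rose from 3.53 ± 0.841 to 39 ± 22.9 FPKM, ISG15 from 5.1 ± 0.757 to 36.5 ± 20.8 FPKM and IFI44 from 0.769 ± 0.13 to 8.83 ± 5.3 FPKM. The AML-A XBP1 libraries, which spread along the leading component, ranged for ISG15 from 16.6 to 58.1 FPKM. For the proliferation marker MKI67, chosen after its values were seen, they ranged from 11 to 21.1 FPKM. Against the control mean, the XBP1 replicates 1, 2 and 3 stood 0.61, 1.35 and 1.04 log2 units higher over the cell cycle list and 0.51, 1.49 and 1.09 over the interferon list. Over the mast cell, basophil and eosinophil markers they stood 0.03, 0.82 and 0.47 higher. In sterol and fatty acid synthesis 9 of 22 genes rose (median 0.34). The sterol list counted 10 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 0.000944 and adjusted p = 0.624 with an estimated correlation. STARD4, a sterol carrier, rose from 6.85 ± 0.986 to 18.8 ± 3.68 FPKM and HMGCS1 from 16.4 ± 1.3 to 40.6 ± 15.4 FPKM. SCD, a fatty acid desaturase, rose from 35.3 ± 1.93 to 63.9 ± 15.6 FPKM and MVD from 12.1 ± 2.28 to 20.7 ± 5.66 FPKM. The XBP1 replicates 1, 2 and 3 stood 0.12, 0.76 and 0.46 log2 units above the control mean of this list. Their mean change was 0.45, and 0.29 without replicate 2.

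In the inflammation and NF-kB list 13 of 22 genes fell in AML-A and 0 rose (limma; median log2 fold change -0.57). The inflammation list counted 1 higher and 14 lower genes adjusted over the list alone, with camera adjusted p = 1.51e-07 and adjusted p = 0.0736 with an estimated correlation. Beside CCL3, the adhesion gene ICAM1 fell from 19.4 ± 0.976 to 4.94 ± 1.71 FPKM and the survival gene BIRC3 from 6.27 ± 0.184 to 1.61 ± 0.143 FPKM. NFKBIA, an inhibitor of NF-kB and itself its target, fell from 153 ± 15.2 to 55.7 ± 5.03 FPKM. Of 32 myeloid differentiation genes 13 were tested, of which 4 fell and 1 rose (median -0.38). The myeloid list counted 1 higher and 4 lower genes adjusted over the list alone, with camera adjusted p = 0.0306 and adjusted p = 0.368 with an estimated correlation. Beside ITGAM, VCAN fell from 2.25 ± 0.448 to 0.641 ± 0.195 FPKM and the lysozyme gene LYZ from 10.9 ± 0.43 to 7.33 ± 0.937 FPKM, while the receptor FCGR2A rose from 33.6 ± 10.4 to 58.7 ± 3.58 FPKM. Of 20 lysosome and autophagy genes 7 fell and 3 rose (median -0.09). The lysosome list counted 3 higher and 7 lower genes adjusted over the list alone, with camera adjusted p = 0.0306 and adjusted p = 0.345 with an estimated correlation. The autophagy receptor SQSTM1 fell from 199.7 ± 5.75 to 112 ± 14.2 FPKM, and CTSA, a lysosomal protease, from 70.2 ± 4.73 to 40.2 ± 0.138 FPKM. LAMP1 fell from 105 ± 6.87 to 66.6 ± 6.02 FPKM, and WIPI1 rose from 25.1 ± 3.23 to 42.2 ± 2.54 FPKM. The myeloid call was lost without AML-A XBP1 replicate 2 (camera adjusted p = 0.115), where the median log2 fold change was -0.07. It was also lost without AML-A control replicate 1 (0.0597) and under quantile normalization (0.0604). The lysosome call was lost without AML-A control replicate 1 (0.0597) or AML-B XBP1 replicate 1 (0.0523). In all, camera called 11 of 28 lists in AML-A, 8 higher and 3 lower. With an estimated correlation it called 0 (6 at an unadjusted p under 0.05), and fry called 14.

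The other gene lists were not called by camera in AML-A, although single members passed the limma test. By fry, MYC and ribosome biogenesis (adjusted p = 0.00601) and phospholipid synthesis (adjusted p = 0.0276) were called higher. Cytosolic heat shock had 2 higher and 4 lower genes of 14, 2 and 5 adjusted over the list alone (camera adjusted p = 0.281). HSPA8, an abundant cytosolic chaperone, fell from 880.1 ± 15.2 to 489 ± 52.8 FPKM, and HSP90AA1 from 343 ± 6.54 to 258 ± 14 FPKM. HSPH1 fell from 95.6 ± 4.86 to 75.9 ± 6.99 FPKM, and BAG3 rose from 5.76 ± 0.53 to 11.7 ± 1.01 FPKM. Stem and progenitor genes had 5 higher and 5 lower genes of 24, 6 and 5 adjusted over the list alone (camera adjusted p = 0.29). The receptor KIT fell from 59.4 ± 4.5 to 24.3 ± 1.67 FPKM and SOX4 from 14.8 ± 0.538 to 9.41 ± 1.35 FPKM. CD93 rose from 7.03 ± 0.303 to 12.7 ± 0.879 FPKM and BAALC from 4.99 ± 0.908 to 8.75 ± 0.284 FPKM. Chromatin regulators of AML had 4 higher and 3 lower genes of 24, 4 and 5 adjusted over the list alone (camera adjusted p = 0.369). The dehydrogenase IDH2 rose from 43.9 ± 1.82 to 159 ± 31.3 FPKM and EZH2 from 13 ± 0.179 to 17.3 ± 2.68 FPKM. MYC and ribosome biogenesis had 9 higher and 2 lower genes of 25, 10 and 2 adjusted over the list alone (camera adjusted p = 0.138). LDHA rose from 216 ± 11.8 to 432 ± 113 FPKM, and TFRC, the transferrin receptor, fell from 112 ± 5.16 to 69.8 ± 8.3 FPKM. Oxidative phosphorylation had 6 higher and 0 lower genes of 26, 5 and 0 adjusted over the list alone (camera adjusted p = 0.125). COX7A2 rose there from 637 ± 21.4 to 921 ± 83.8 FPKM. The AP-1 and early response list had 6 higher and 1 lower genes of 19, 6 and 1 adjusted over the list alone (camera adjusted p = 0.68). FOSB rose from 2.12 ± 0.0366 to 8.85 ± 0.751 FPKM, EGR3 from 1.58 ± 0.0781 to 5.87 ± 1.25 FPKM and FOS from 2.22 ± 0.383 to 4.97 ± 0.544 FPKM, while IER3 fell from 2.67 ± 0.639 to 0.933 ± 0.181 FPKM. Apoptosis and p53 targets had 5 higher and 5 lower genes of 23, 5 and 6 adjusted over the list alone (camera adjusted p = 0.457). BTG2 fell from 44.4 ± 1.33 to 24.2 ± 0.893 FPKM, and CDKN1A, a p53 target that restrains the cell cycle, rose from 45.4 ± 1.15 to 68.1 ± 2.52 FPKM. Phospholipid synthesis had 4 higher and 2 lower genes of 19, 4 and 2 adjusted over the list alone (camera adjusted p = 0.793). PEMT rose from 17.3 ± 2.76 to 26.7 ± 2.07 FPKM, and CEPT1 fell from 25.1 ± 1.09 to 17.5 ± 1.5 FPKM. Known substrates of IRE1-dependent decay had 2 higher and 1 lower genes of 9, 2 and 1 adjusted over the list alone (camera adjusted p = 0.691). PDGFRB rose from 11.1 ± 0.521 to 16.9 ± 3.27 FPKM, and SUMF1 fell from 7.17 ± 0.274 to 5.7 ± 0.237 FPKM. The MYC list was called higher without AML-A XBP1 replicate 2 (adjusted p = 0.0491), and oxidative phosphorylation without AML-A XBP1 replicate 1 (0.0202).

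Markers of other cell types were not called as lists by camera in AML-A either, while fry called the B cell and plasma cell list higher (adjusted p = 0.00116). Many markers did not pass the filter. Tested were 6 of 16 B cell, 10 of 19 T and NK cell, 7 of 16 erythroid and 7 of 12 megakaryocyte markers. Of the mast cell, dendritic cell and stromal lists 5, 5 and 4 of 12 markers were tested. In the B cell and plasma cell list MZB1 passed the test, alone among 6. That list had 1 higher and 0 lower genes of 6, 1 and 1 adjusted over the list alone (camera adjusted p = 0.68). The T cell and NK cell list had 3 higher and 1 lower genes of 10, 3 and 1 adjusted over the list alone (camera adjusted p = 0.68). CD3D, a subunit of the T cell receptor complex, rose from 2.31 ± 0.325 to 13.2 ± 3.01 FPKM and GZMB from 0.361 ± 0.189 to 3.43 ± 2.1 FPKM. The T cell kinase LCK fell from 1.58 ± 0.342 to 0.757 ± 0.281 FPKM. The megakaryocyte and platelet list had 2 higher and 0 lower genes of 7, 2 and 0 adjusted over the list alone (camera adjusted p = 0.281). GP9 rose from 5.33 ± 0.553 to 17.6 ± 3.62 FPKM and VWF from 5.97 ± 0.425 to 13.3 ± 3.07 FPKM. The mast cell, basophil and eosinophil list had 2 higher and 0 lower genes of 5, 2 and 0 adjusted over the list alone (camera adjusted p = 0.968). FCER1A, a chain of the IgE receptor, rose from 27.1 ± 3.11 to 122 ± 37.5 FPKM. HDC, the enzyme of histamine synthesis, rose from 35 ± 2.65 to 96.8 ± 44.8 FPKM. The median log2 fold change of this list was -0.27 and its mean 0.44. The erythroid list had 1 higher and 0 lower genes of 7, 1 and 0 adjusted over the list alone (camera adjusted p = 0.914). The dendritic cell list had 1 higher and 1 lower genes of 5, 1 and 1 adjusted over the list alone (camera adjusted p = 0.805). The stromal and endothelial list had 1 higher and 2 lower genes of 4, 1 and 2 adjusted over the list alone (camera adjusted p = 0.858).

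**Figure D2:**
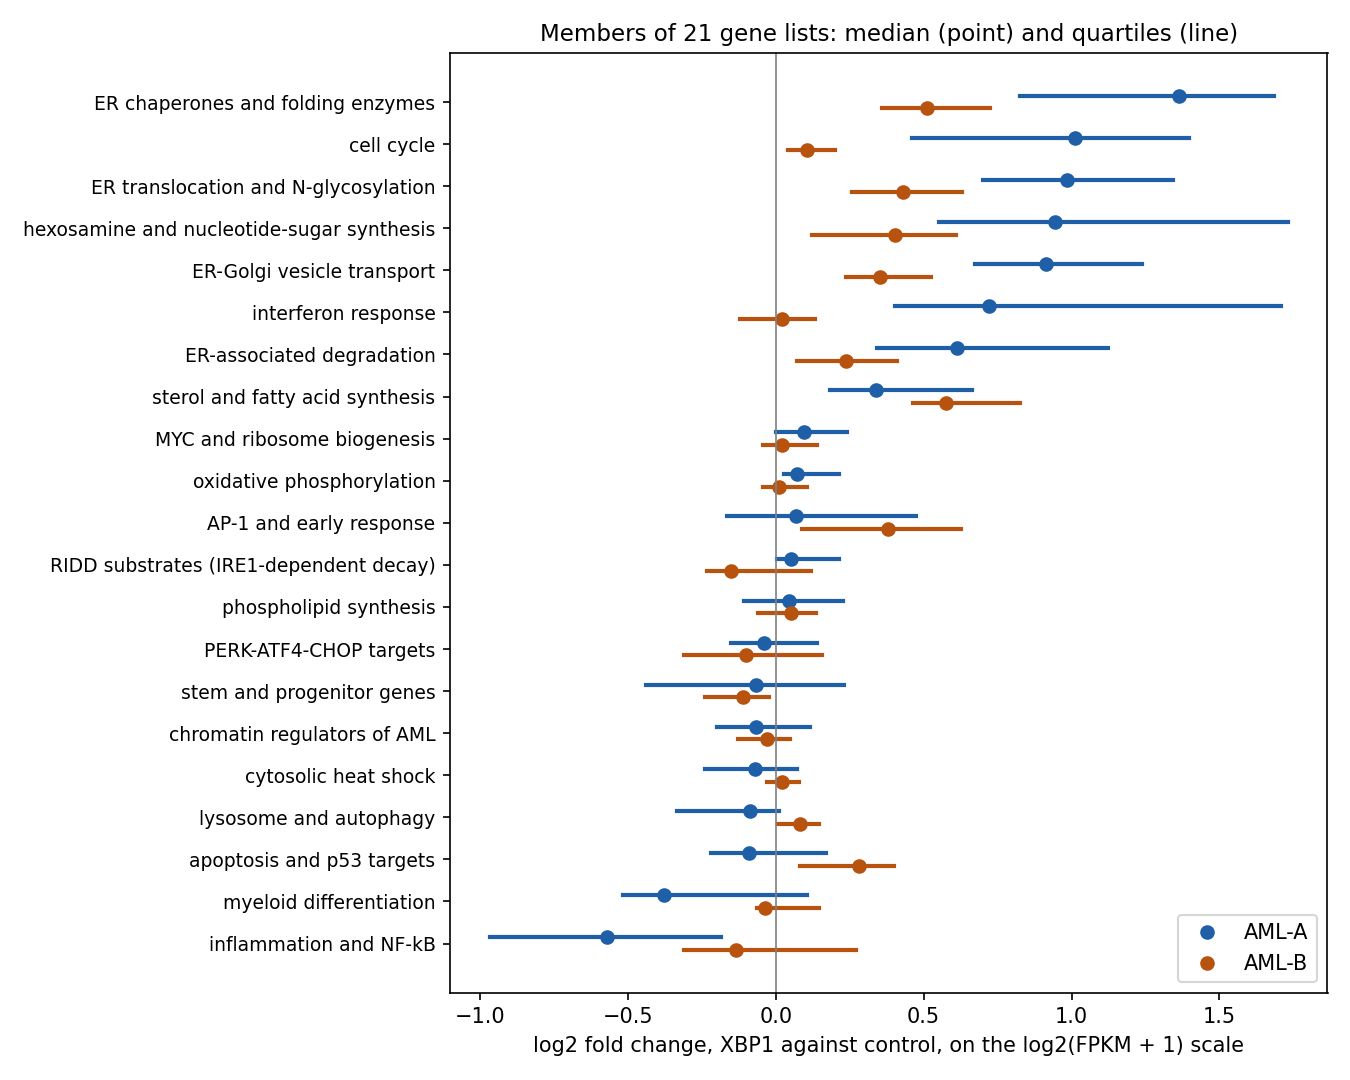
Log2 fold change of XBP1 against control libraries, on the log2(FPKM + 1) scale, over the members of 21 gene lists in AML-A (blue) and AML-B (orange); points are medians over genes and lines span the quartiles. ER chaperones and folding enzymes had the highest median in AML-A, 1.36, against 0.51 in AML-B, and the cell cycle list stood at 1.01 and 0.11.

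In AML-B fewer genes passed the test than in AML-A. SEC24D rose from 6.88 ± 1.31 to 37.3 ± 18.3 FPKM, a log2 fold change of 2.19 ± 0.24 (adjusted p = 0.00194, limma). MEI1 rose from 2.23 ± 0.253 to 13.4 ± 5.47 FPKM (2.09 ± 0.22) and MZB1 from 1.25 ± 0.781 to 5.79 ± 1.28 FPKM (1.63 ± 0.20). FOS, an immediate early transcription factor, rose from 3.51 ± 1.89 to 12 ± 4.59 FPKM. CHPF, an enzyme of chondroitin synthesis, rose from 2.18 ± 0.487 to 8.43 ± 2.69 FPKM, and the lectin LGALS1 from 87.5 ± 8.53 to 238 ± 43.5 FPKM. PPAP2A (PLPP1 in GENCODE 29) rose from 1.29 ± 0.35 to 5.87 ± 2.92 FPKM and the prion protein gene PRNP from 1.61 ± 0.219 to 6.28 ± 1.62 FPKM. TMEM255B rose from 1.71 ± 0.704 to 5.93 ± 1.59 FPKM, and AL049542.1, an ID that GENCODE 29 does not hold, from 0.0888 ± 0.154 to 5.56 ± 2.6 FPKM. Besides IL2RA, PLVAP, an endothelial membrane protein, fell from 8.95 ± 0.854 to 1.35 ± 0.773 FPKM, a log2 fold change of -2.13 ± 0.17. GTSF1 fell from 3.89 ± 1.85 to 0.142 ± 0.134 FPKM and APOC2 from 4.6 ± 1.84 to 0.493 ± 0.575 FPKM. The dehydrogenase ALDH2 fell from 13.1 ± 1.09 to 4.68 ± 2.52 FPKM and the scavenger receptor STAB1 from 4.07 ± 0.737 to 1.04 ± 0.0566 FPKM. The spectrin gene SPTBN1 fell from 26.9 ± 3.31 to 11.7 ± 5.59 FPKM and TM4SF1 from 5.37 ± 0.818 to 2.14 ± 1.06 FPKM. The pseudogene POLR2KP1, which shares sequence with its parent gene, fell from 12.4 ± 4.93 to 1.59 ± 1.76 FPKM.

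The AML-B test called 490 of 15116 genes (limma, adjusted p under 0.05), 403 higher and 87 lower, and 54 by at least 2-fold (41 higher, 13 lower). Quantile normalization gave 270 higher and 107 lower, 71.6% higher in place of 82.2%. The count was 10 with AML-B fitted alone, 73 with the replicate block and 123 with no filter on low values. It was 76 and 83 without AML-B control replicate 2 or 3, 218 without AML-B XBP1 replicate 3, 315, 264 and 272 without AML-A control replicate 1, 2 or 3, and 273 without AML-A XBP1 replicate 3, since all libraries share the estimate of the spread. Of 62 genes that the rule for named genes or the lists took for AML-B, 56 missed the threshold with AML-B fitted alone and 40 without AML-B control replicate 2, while SEC24D, MEI1, MZB1, CHPF, PRNP, TMEM255B, PLVAP, GTSF1, STAB1 and LGALS1 kept their call without any single library.

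The 5 lists of ER and secretory functions were called higher in AML-B too. Of 24 ER chaperones and folding enzymes 12 rose (median log2 fold change 0.51). In AML-B the chaperone list counted 20 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 5.09e-17 and adjusted p = 0.16 with an estimated correlation. SDF2L1 rose from 5.99 ± 0.922 to 15.2 ± 2.71 FPKM, CRELD2 from 10.1 ± 0.567 to 24.7 ± 4.64 FPKM and MANF from 100.2 ± 4.1 to 195 ± 54.1 FPKM. In ER translocation and N-glycosylation 18 of 31 genes rose (median 0.43). In AML-B the translocation list counted 25 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 6.18e-18 and adjusted p = 0.16 with an estimated correlation. SEC11C rose from 33.1 ± 1.81 to 75.2 ± 26.6 FPKM, and SSR3 from 72.7 ± 4.53 to 152 ± 55.7 FPKM. SEC61B, a translocon subunit, rose from 106 ± 4.67 to 205 ± 59.8 FPKM. In ER-Golgi vesicle transport 14 of 35 genes rose (median 0.35). In AML-B the transport list counted 30 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 1.76e-18 and adjusted p = 0.16 with an estimated correlation. The coatomer gene COPE rose from 191 ± 53.5 to 391 ± 68.3 FPKM and KDELR3 from 2.49 ± 0.483 to 8.35 ± 4.41 FPKM. In ER-associated degradation 4 of 21 genes rose (median 0.24). In AML-B the degradation list counted 11 higher and 1 lower genes adjusted over the list alone, with camera adjusted p = 1.01e-05 and adjusted p = 0.16 with an estimated correlation. DERL3 rose from 11.6 ± 1.29 to 28.1 ± 8.44 FPKM and ERLEC1 from 19.3 ± 0.48 to 34.5 ± 10.2 FPKM. In hexosamine and nucleotide-sugar synthesis 3 of 13 genes rose (median 0.40). In AML-B the hexosamine list counted 6 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 0.000186 and adjusted p = 0.16 with an estimated correlation. GMPPB rose from 3.25 ± 0.206 to 8.38 ± 3.26 FPKM and GMPPA from 24.3 ± 0.827 to 52 ± 22.5 FPKM. The AML-B XBP1 replicates 1, 2 and 3 stood 0.34, 0.20 and 0.72 log2 units above the control mean of the hexosamine list. Their mean change was 0.42, and 0.27 without replicate 3. The same replicates stood 0.51, 0.32 and 0.91 higher over the chaperone list, 0.36, 0.28 and 0.71 over the translocation list and 0.37, 0.30 and 0.70 over the transport list.

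The sterol, early response and p53 target lists were also called higher in AML-B. In sterol and fatty acid synthesis 7 of 22 genes rose (median log2 fold change 0.57). The lipid list counted 15 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 3.23e-11 and adjusted p = 0.216 with an estimated correlation. FASN, the fatty acid synthase, rose from 53.1 ± 10.5 to 105 ± 14 FPKM. MVD rose from 23.1 ± 4.46 to 47.3 ± 5.67 FPKM and HMGCS1 from 55.1 ± 9.48 to 104 ± 10.3 FPKM, both of the mevalonate pathway. Of 19 AP-1 and early response genes 5 rose (median 0.38). The early response list counted 8 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 2.79e-06 and adjusted p = 0.16 with an estimated correlation. Beside FOS, its partner JUN rose from 0.843 ± 0.304 to 3.04 ± 1.6 FPKM, and ZFP36 from 8.67 ± 0.637 to 15.4 ± 0.289 FPKM. Of 23 apoptosis and p53 targets 2 rose (median 0.28). The p53 target list counted 8 higher and 0 lower genes adjusted over the list alone, with camera adjusted p = 2.53e-05 and adjusted p = 0.16 with an estimated correlation. CDKN1A rose from 21.6 ± 1.3 to 48.1 ± 8.0 FPKM and BAX, which promotes apoptosis, from 322 ± 23 to 425 ± 30 FPKM. Stem and progenitor genes were called lower, with 2 of 24 past the test (median -0.11). The stem list counted 0 higher and 2 lower genes adjusted over the list alone, with camera adjusted p = 0.0153 and adjusted p = 0.233 with an estimated correlation. ERG fell from 18.4 ± 1.57 to 11.1 ± 3.02 FPKM and PBX3 from 17.1 ± 0.525 to 12.8 ± 1.31 FPKM. That call was lost without AML-B control replicate 1 (adjusted p = 0.102) or AML-B XBP1 replicate 1 (0.105). In all, camera called 9 of 28 lists in AML-B, 8 higher and 1 lower. With an estimated correlation it called 0 (7 at an unadjusted p under 0.05), and fry called 8.

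The remaining lists were not called by camera in AML-B. The cell cycle list of AML-B had 0 higher and 0 lower genes of 30 (limma; 2 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.227). MCM7, a replication factor, stood at 313 FPKM in the controls and 329.8 with XBP1. The interferon response had 0 higher and 1 lower genes of 22, 0 and 1 adjusted over the list alone (camera adjusted p = 0.599). CXCL10 fell from 1.28 ± 0.439 to 0.276 ± 0.113 FPKM. Inflammation and NF-kB had 2 higher and 2 lower genes of 22, 4 and 5 adjusted over the list alone (camera adjusted p = 0.334). IL8 rose from 4.31 ± 0.596 to 12 ± 3.27 FPKM, and TNFAIP3, a brake on NF-kB, fell from 11.2 ± 1.52 to 6.14 ± 0.724 FPKM. PERK targets had 0 higher and 0 lower genes of 22 (limma; 7 at an unadjusted p under 0.05), 1 and 4 adjusted over the list alone (camera adjusted p = 0.138). ATF4 stood at 275 ± 6.96 and 291 ± 23.1 FPKM. Lysosome and autophagy had 1 higher and 0 lower genes of 20, 1 and 0 adjusted over the list alone (camera adjusted p = 0.182). Myeloid differentiation had 0 higher and 0 lower genes of 13 (limma; 3 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.7). The surface marker CD33 stood at 93.7 and 91.1 FPKM. Chromatin regulators in AML-B had 0 higher and 1 lower genes of 24, 0 and 1 adjusted over the list alone (camera adjusted p = 0.182). KMT2A fell from 18.3 ± 1.53 to 14.3 ± 1.27 FPKM. Heat shock genes had 0 higher and 0 lower genes of 14 (limma; 3 at an unadjusted p under 0.05), 1 and 0 adjusted over the list alone (camera adjusted p = 0.599). HSPA8 stood at 1043 ± 72.9 and 1046 ± 117 FPKM. The MYC list had 2 higher and 0 lower genes of 25, 3 and 0 adjusted over the list alone (camera adjusted p = 0.549). Oxidative phosphorylation in AML-B had 0 higher and 0 lower genes of 26 (limma; 2 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.698). Phospholipid synthesis in AML-B had 0 higher and 0 lower genes of 19 (limma; 3 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.599). Substrates of IRE1-dependent decay had 1 higher and 0 lower genes of 9, 1 and 1 adjusted over the list alone (camera adjusted p = 0.599). PMP22 rose from 17.9 ± 1.64 to 25.6 ± 3.4 FPKM.

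No marker list was called by camera in AML-B either, over the same tested markers. The B cell and plasma cell list had 2 higher and 0 lower genes of 6, 2 and 1 adjusted over the list alone (camera adjusted p = 0.928). IGJ (the joining chain of immunoglobulins) rose from 0.297 ± 0.152 to 1.42 ± 0.656 FPKM beside MZB1. T cell and NK cell markers had 1 higher and 1 lower genes of 10, 1 and 1 adjusted over the list alone (camera adjusted p = 0.897). CD3D fell from 1.85 ± 0.344 to 0.546 ± 0.35 FPKM and NCAM1 rose from 93.9 ± 5.47 to 129 ± 19.8 FPKM. Stromal and endothelial markers had 1 higher and 0 lower genes of 4, 1 and 1 adjusted over the list alone (camera adjusted p = 0.698). PDGFRA rose from 0.177 ± 0.118 to 1.18 ± 0.219 FPKM. Erythroid markers had 0 higher and 0 lower genes of 7 (limma; 0 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.599). Megakaryocyte and platelet markers had 0 higher and 0 lower genes of 7 (limma; 3 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.334). Mast cell, basophil and eosinophil markers had 0 higher and 0 lower genes of 5 (limma; 2 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.0957). Dendritic cell markers had 0 higher and 0 lower genes of 5 (limma; 0 at an unadjusted p under 0.05), 0 and 0 adjusted over the list alone (camera adjusted p = 0.599). Some lists were called in AML-B when a library was left out. The cell cycle list was called higher without AML-B XBP1 replicate 1 (adjusted p = 0.00923), and the megakaryocyte list lower (0.00717). PERK targets and chromatin regulators were called lower without AML-B control replicate 3 (0.019 and 0.0315), and the lysosome list higher without AML-B XBP1 replicate 3 (0.0404). The mast cell list was called higher without AML-B control replicate 2 (0.0261) or AML-B XBP1 replicate 2 or 3 (0.00834 and 0.046).

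Genes of the secretory pathway were among those higher in both AML samples. Averaged over AML-A and AML-B, MZB1, MEI1 and SEC24D had log2 fold changes of 3.17 ± 0.14, 3.07 ± 0.16 and 2.85 ± 0.17, followed by KDELR3 (2.41 ± 0.18), ANG (2.21 ± 0.16), PDIA2 (2.19 ± 0.23), DERL3 (2.12 ± 0.12), GMPPB (1.95 ± 0.13) and the exonuclease gene ISG20 (1.82 ± 0.13). In the other direction were IL32 (-2.11 ± 0.35), PLVAP (-1.66 ± 0.12), ALDH2 (-1.49 ± 0.20), the matrix protease MMP9 (-1.16 ± 0.20), M1AP (-1.02 ± 0.15) and the NF-kB regulators BIRC3 (-1.0 ± 0.08) and BCL3 (-0.96 ± 0.09), besides IL2RA and the pseudogenes POLR2KP1 (-1.74 ± 0.35) and CTD-2319I12.1 (-1.45 ± 0.22). Each passed the limma test of the average, with adjusted p of at most 0.00476. That test does not show a change in AML-B by itself. The average contrast called 3896 genes, 2458 higher and 1438 lower (1882 and 2283 after quantile normalization). Of the genes called in each AML sample, 248 were higher in both, where independent lists of those sizes would share 69.6, and 34 were lower in both, against 10. Another 13 went in opposite directions. The contrasts share no library but share the estimate of the spread of each gene, so that their calls are not independent. The vector genes XBP1 and IL2RA are counted among the shared genes. Across the 15116 genes, which are not independent replicates, the fold changes correlated at Pearson's r = 0.40 (0.36 without IL2RA) and Spearman's rho = 0.33. The shared count of 282 genes was 5 with each AML sample fitted alone. It was 176, 52 and 57 without AML-B control replicate 1, 2 or 3, 121 without AML-B XBP1 replicate 3, 174, 139 and 147 without AML-A control replicate 1, 2 or 3, and 150 without AML-A XBP1 replicate 3.

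The effect of XBP1 against the CD25 control differed between AML-A and AML-B for part of the genes. MZB1, PGM3, IFI27 and CD3D had the more positive effect in AML-A, with log2 differences (AML-B effect minus AML-A effect) of -3.07 ± 0.29, -2.99 ± 0.64, -2.96 ± 0.77 and -2.98 ± 0.26. SPP1 and CD74 had the more positive effect in AML-B, by 3.33 ± 0.44 and 2.95 ± 0.54. So had the processed pseudogenes RP11-348H3.5 (2.46 ± 0.58) and RPL39P5 (2.24 ± 0.36) and the long noncoding AP001029.1 (2.43 ± 0.62, ENSG00000267108.1, by its GENCODE 29 symbol). In AML-A SPP1 and CD74 fell, with log2 fold changes of -2.46 and -2.04. In AML-B SPP1 stood at 0.418 ± 0.217 and 1.73 ± 1.08 FPKM in control and XBP1 libraries, and CD74 at 1.31 ± 0.609 and 3.79 ± 2.925. The highest group means of RP11-348H3.5, RPL39P5 and AP001029.1 were 1.84, 1.9 and 3.12 FPKM. The interaction contrast of limma called 1357 genes, 829 more positive in AML-A and 528 more positive in AML-B; 1217 of them were also called in AML-A. The count was 793 with no filter on low values, 649 with the replicate block, 2922 with library weights, 763 and 710 without AML-A control replicate 2 or 3, 702 without AML-A XBP1 replicate 3, and 737 and 784 without AML-B control replicate 2 or 3. The IFI27 and AP001029.1 differences missed the threshold without most single libraries (adjusted p up to 0.0846 and 0.0819), and that of RP11-348H3.5 without 5 of them (up to 0.0603). The rule named 11 genes with a called difference, XBP1 among them. Of the 11 calls, 5 were lost with no filter on low values. Another count was 4, without AML-A control replicate 2, AML-A XBP1 replicate 3 or AML-B control replicate 3, so that calls of further named genes were lost too. By camera, 12 of 28 lists differed. With an estimated correlation 0 did (6 at an unadjusted p under 0.05), and by fry 13. ER chaperones (14 of 24 genes, adjusted p = 1.81e-13, adjusted p = 0.218 with an estimated correlation) and ER-Golgi transport (22 of 35, adjusted p = 2.68e-15, adjusted p = 0.206 with an estimated correlation) were more positive in AML-A. So were the cell cycle (15 of 30, adjusted p = 2.48e-13, adjusted p = 0.306 with an estimated correlation) and interferon lists (7 of 22, adjusted p = 7.48e-07, adjusted p = 0.306 with an estimated correlation). The inflammation and NF-kB list was more positive in AML-B (8 of 22, adjusted p = 3.14e-08, adjusted p = 0.0539 with an estimated correlation), led by CCL3 (2.08 ± 0.21), ICAM1 (1.49 ± 0.34) and NFKBIA (1.22 ± 0.14). Sterol and fatty acid synthesis did not pass this test (adjusted p = 0.351), FASN being the sole member past the test, more positive in AML-B (0.89 ± 0.22).

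**Figure D3:**
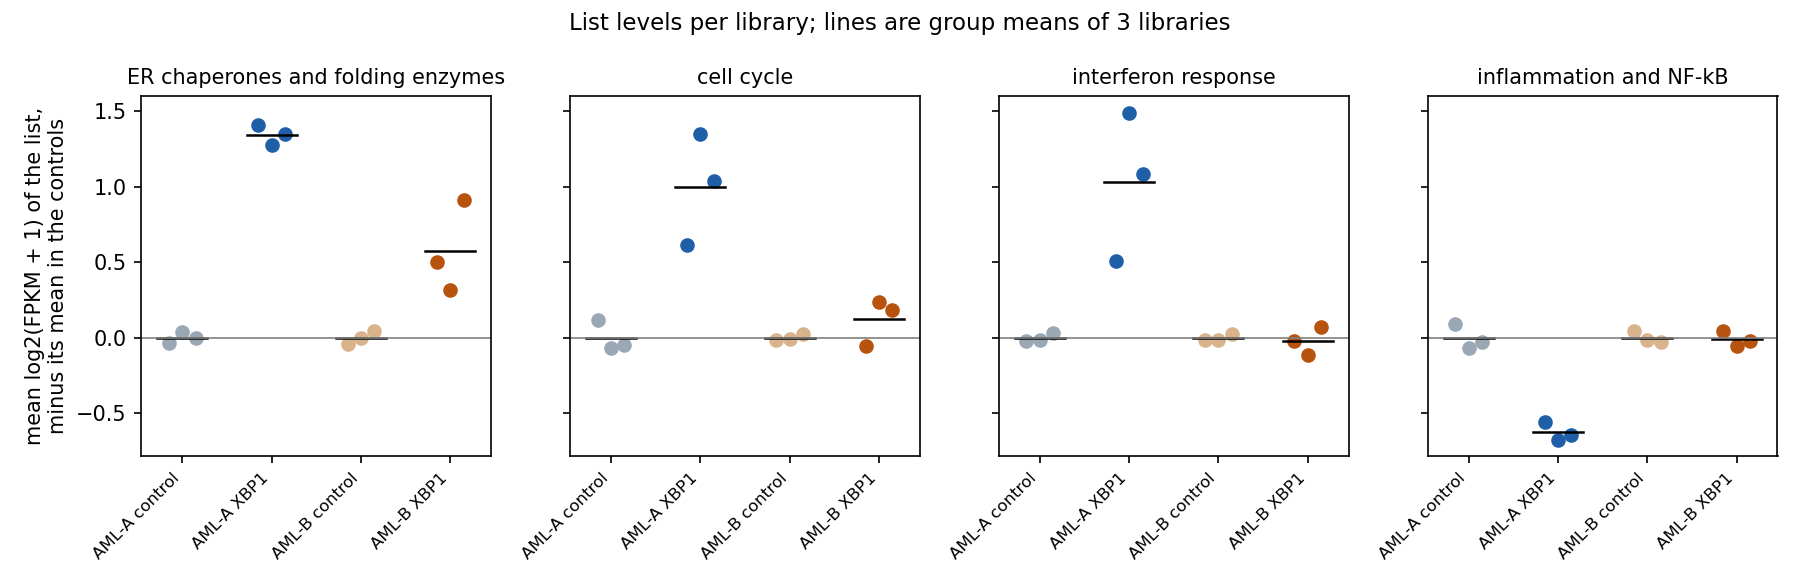
Mean log2(FPKM + 1) over the members of 4 lists in each library, minus the mean of the 3 control libraries of the same AML sample (points, colored by group; lines are means of 3 libraries). The cell cycle list rose by 1.0 on average in AML-A and stood at 0.12 in AML-B, and the interferon list at 1.03 and -0.02.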

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

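Among the tests of explanations and the splits of the libraries in this part, all but the one on genes at least 8-fold higher in the AML-B controls were chosen only after the result was seen.

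The effect of XBP1 against the CD25 control differed between AML-A and AML-B, by the test of the difference itself, for 1357 genes. XBP1 itself was among them, with a log2 difference (AML-B effect minus AML-A effect) of -0.82, near the threshold (limma, adjusted p = 0.0399). The effect was more positive in AML-B for SPP1 (3.33), CD74 (2.95), RP11-348H3.5 (2.46), AP001029.1 (2.43) and RPL39P5 (2.24). SPP1 and CD74 fell in AML-A and lay at low FPKM in AML-B, and the noncoding genes lay at low FPKM throughout. The effect was more positive in AML-A for MZB1 (-3.07), PGM3 (-2.99), CD3D (-2.98) and IFI27 (-2.96). The fitted value of -7.31 for AL132780.1 depends on the pseudocount, since the gene was listed near 0 in the AML-A controls, and is no bound, and whether it is a gene of a small RNA, with unreliable values, is unknown. By camera on the difference, 12 lists stood out with median log2 differences of -0.70 for ER chaperones, -0.46 for ER-associated degradation, -0.53 for translocation and N-glycosylation, -0.58 for ER-Golgi transport, -0.58 for hexosamine synthesis, -0.98 for the cell cycle, -0.67 for interferon and -0.71 for megakaryocytes. The lysosome list stood at 0.21, apoptosis and p53 targets at 0.39, myeloid differentiation at 0.26 and inflammation and NF-kB at 0.43. With an estimated correlation none of these lists was called by camera (adjusted p = 0.0539 for inflammation and NF-kB to 0.491 for megakaryocytes).

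For the 1357 genes, 6 of 100 splits of the libraries within the AML samples, the real one included, gave as many, with up to 2156 in another split, so that chance is not excluded by this count. The other splits as large all kept the AML-A libraries as labelled and mixed those of AML-B, which leaves the AML-A effect in the contrast, while splits that mixed AML-A gave at most 3. A smaller rise of XBP1 RNA in AML-B may account for the endoplasmic reticulum lists. The comparison used log2 changes of total XBP1 RNA, which stood at 127.8 and 105.5 FPKM in the AML-A and AML-B controls. Another scale was not tested. The test asked only whether the leave-one-out ranges overlap, which cannot decide it. The mean change of these lists in AML-B over that in AML-A was 0.419 (0.302 to 0.504 leaving out each library), next to 0.454 (0.368 to 0.598) for XBP1. The same ratio was 0.0613 (0.0236 to 0.113) for the cell cycle and interferon lists, which argues against one scaled response for them; the cell cycle list was already 0.65 log2 units higher in the AML-B controls than in the AML-A XBP1 libraries, while the interferon list was at -0.80, so that a high starting level stays open only for the cell cycle. The patient, the cytokines of the medium and the level of CD25 in the controls remain untested, since the design confounds them.

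On the leading principal component the AML-A XBP1 libraries lay nearer those of AML-B than the AML-A controls did. If RNA of AML-B cells were the source, the cell cycle genes over 2-fold higher in AML-B would need a median share of 41% of it by the AML-B controls (21 genes) and 36.6% by the AML-B XBP1 libraries (22 genes). IL2RA in the AML-A XBP1 libraries stood at 0.1% of its level in the AML-B controls, which argues against RNA of AML-B control cells, and MZB1 and SEC24D stood higher there (35.9 and 99.7 FPKM) than in the AML-B XBP1 libraries (5.79 and 37.3), a level that RNA of AML-B cells cannot give. The interferon list had a mean log2 level of 3.62 ± 0.49 in the AML-A XBP1 libraries. It stood at 2.83 ± 0.02 in the AML-B controls and 2.81 ± 0.09 in the AML-B XBP1 libraries. These levels argue against RNA of AML-B cells as the source of the interferon rise. For other genes RNA of AML-B XBP1 cells stays open. One set held genes at least 4-fold higher in the AML-B XBP1 libraries than in an AML-A control library, at 20 FPKM or more. Without genes called in AML-B it had 73 to 86 genes over the choices of that library. Its median shares were 30.4% to 32% against the other controls, where a control in place of the XBP1 libraries gave -3.17% to 3.27%. Cell cycle list genes were not taken out of this set, so that it is not separate from the genes behind the share needed. The 7 genes at least 8-fold higher in the AML-B controls, in no list, gave 34.2% (quartiles 12.1% and 66.1%). Chosen the same way, 11 to 13 such genes gave medians of 23.8% to 29.4%, with quartiles reaching from -61.3% to 69.9%. Such RNA and an effect of XBP1 could each give these medians, and quartiles so wide do not decide between them. Lineage genes do not settle it. Their medians were 9.46% (0.365% and 15.4%) over 10 genes by the AML-B controls. By the AML-B XBP1 libraries they were 10.1% (0.433% and 23.9%) over 8 genes, MZB1 left out. These medians go against such RNA. Among the 8 genes MYB (0.353%), KLF1 (0.46%) and ERG (-4.11%) hardly rose or fell, while HDC (53.4%) and VWF (57.1%) lay above the share needed. Under that share lay 8 and 6 genes (exact sign test, two-sided p = 0.109 and 0.289). The sign test counts genes as replicates and has few of them, so that it cannot decide. Such RNA and an effect of XBP1 on the cell cycle genes both stay open.

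CD3D rose in AML-A and fell in AML-B. T cells among the sorted AML-A XBP1 cells were tested with CD3E, LCK and ZAP70 of the marker list, whose mean log2 change was -0.24 against 2.08 for CD3D (SE of the difference 0.21). These 3 genes lay under 2 FPKM in both groups, and GZMB of the same list rose from 0.361 ± 0.189 to 3.43 ± 2.1 FPKM, so that T cells or NK cells are not excluded. The sort for ZsGreen would leave out those that took up no vector. No biological explanation was tested.

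Splits of the libraries were also counted for the other comparisons. In AML-A 1 of 10 splits gave as many genes, the real one with 4345 and the highest other with 1. In AML-B it was 1 of 10, with 490 and 2 genes, and 10 splits are too few for a share under 0.05. For the mean, 1 of 100 splits gave as many, the real one with 3896 genes against at most 2258 in another. By this count a chance split of these libraries is unlikely but not excluded.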

How the results depend on the processing

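The test on protein-coding genes was chosen only after the result was seen. Over all alternatives, genes taken by the rule for named genes kept their side of the threshold in 4288 comparisons. A change of direction that passed the threshold in neither setting was counted among these. Genes missed the threshold in 504 comparisons, passed it newly in 1 and reversed in 1: the IL2RA difference was -0.59 under quantile normalization. The cause of these changes was not tested. No filter adds genes to adjust for, and AML-B fitted alone or with a library less has fewer libraries for the spread. AML-A fitted alone has as few, and 1 of its 104 genes lost its call, against 56 of 62 in AML-B. The losses in AML-B thus do not follow from the number of libraries alone. Read depth, which is unknown, limits the low values.

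The AML-A count was 6881 with library weights, whose estimation stopped short of its default tolerance. Without a filter there were 123 genes in AML-B, 793 in the difference and 63 shared. With the replicate block these were 73, 649 and 48. Deviations of libraries with the same number correlated at 0.048, 0.034 and -0.002 in AML-A and -0.078, 0.094 and 0.033 in AML-B, so that the numbers do not pair them. Fitted alone, AML-A gave 4113 genes and AML-B 10, and the shared count was 5. Library weights gave 2922 differing genes. A 2-fold minimum left 471 (AML-A), 54 (AML-B), 142 (mean) and 274 (difference). XBP1 in AML-B missed the threshold with a log2 fold change of 0.68 without a filter (adjusted p = 0.14), with the block (0.0862), fitted alone (0.131) and without trend and robust settings (0.0525), with 0.66 under median-ratio scaling (0.0521) and with 0.63 under quantile normalization (0.0539).

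Leaving out each library, the counts ran over 3062 to 4589 in AML-A, 76 to 616 in AML-B (lowest without AML-B control replicate 2), 2962 to 4240 in the mean, 702 to 1785 in the difference (lowest without AML-A XBP1 replicate 3) and 52 to 329 shared. List calls ran over 9 to 13 in AML-A and 8 to 11 in AML-B. XBP1 ran over 1.38 to 1.60 and 0.55 to 0.89, IL2RA over -10.68 to -10.52 and -10.56 to -10.35.

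With an estimated correlation camera called 0 lists in AML-A and 0 in AML-B, with adjusted p in AML-A of 0.14 (ER chaperones, translocation), 0.115 (ER-associated degradation), 0.133 (ER-Golgi transport, hexosamine), 0.624 (sterol), 0.345 (lysosome), 0.368 (cell cycle, myeloid), 0.472 (interferon) and 0.0736 (NF-kB), and in AML-B of 0.16 (ER chaperones, ER-associated degradation, translocation, ER-Golgi transport, hexosamine, p53 targets, AP-1), 0.216 (sterol) and 0.233 (stem). By fry, lists newly called in AML-A were phospholipid (0.0276), MYC (0.00601) and B cell (0.00116), and the stem list in AML-B missed the threshold (0.0987). Without a filter MYC (0.00474) and oxidative phosphorylation (0.0164) in AML-A and lysosome (0.0167) in AML-B were called higher, myeloid was not called in AML-A (0.143) and turned to higher in AML-B (0.0349). Library weights called oxidative phosphorylation in AML-A (0.0221) and PERK in AML-B (0.0155, lower). Fitted alone, lysosome (0.0522) and myeloid (0.0543) lost their call in AML-A and cell cycle was called in AML-B (0.0217). Quantile normalization ended the myeloid call in AML-A (0.0604), and the filter at 5 FPKM gave NF-kB a lower call in AML-B (0.0196).

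Leaving out each library, adjusted p in AML-A ran over ER chaperones 1.09e-23 to 1.22e-16, ER-associated degradation 4.38e-10 to 2.87e-07, translocation 1.4e-25 to 2.27e-17, ER-Golgi transport 1.22e-26 to 1.01e-18, hexosamine 4.04e-08 to 2.25e-05, phospholipid 0.636 to 0.847, sterol 3.48e-06 to 0.0238, PERK 0.0202 to 0.894, lysosome 0.0166 to 0.0597, cell cycle 5.82e-19 to 4.35e-12, MYC 0.0491 to 0.326, oxidative phosphorylation 0.0202 to 0.318, myeloid 0.00378 to 0.115, interferon 1.23e-08 to 7.41e-05, NF-kB 4.77e-08 to 9.95e-07 and B cell 0.538 to 0.846. The PERK list turned to higher without AML-A XBP1 replicate 2 (0.0243). In AML-B it ran over ER chaperones 5.87e-24 to 1.64e-13, ER-associated degradation 4.11e-08 to 0.000188, translocation 2.66e-23 to 7.59e-14, ER-Golgi transport 2.12e-23 to 6.25e-15, hexosamine 2.14e-05 to 0.00216, sterol 3.16e-14 to 4.36e-07, PERK 0.019 to 0.365, lysosome 0.0404 to 0.427, cell cycle 0.00923 to 0.919, p53 targets 1.78e-05 to 0.00128, stem 0.00189 to 0.105, myeloid 0.342 to 0.963, NF-kB 0.213 to 0.568, AP-1 6.6e-07 to 4.02e-05, chromatin 0.0315 to 0.416, megakaryocyte 0.00717 to 0.985 and mast cell 0.00834 to 0.601.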

Other observations

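The AML-A XBP1 libraries differed among themselves in stress and interferon genes, which were chosen after their values were seen. XBP1 stood at 425, 312 and 359 FPKM in replicates 1, 2 and 3, and the ER chaperone gene HSPA5 at 395, 279 and 323. ATF4, the transcription factor of the PERK branch, stood at 709, 498 and 641 FPKM, with AML-A controls at 549 ± 12.2. ASNS (asparagine synthetase), a target of ATF4, stood at 165, 78 and 136 (controls 112 ± 1.6), and the pseudokinase gene TRIB3 at 70.5, 24.7 and 43.9 (controls 39.6 ± 1.12). The interferon-induced genes IFI27 and IFI6 stood at 3.84, 35.6 and 18.4 (controls 0.68 ± 0.327) and at 16.3, 62.1 and 38.5 FPKM (controls 3.53 ± 0.841) in the same libraries. With 3 libraries no relation between these genes was tested.

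The controls of the AML samples also differed in their starting levels, a difference that the design confounds with patient and medium and that was not tested. The cell cycle list had a mean log2(FPKM + 1) of 4.36 ± 0.10 in the AML-A controls and 6.01 ± 0.02 in the AML-B controls (SD, n = 3). The interferon list stood at 2.60 ± 0.03 and 2.83 ± 0.02.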
